A study of Mus musculus with 6 samples.

How the data were processed

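RNA was extracted from NIH-3T3 cells and from a mutated derivative of that line, and poly(A) RNA libraries were made with a kit that marks the strand, per the labels. There were 3 libraries of the unmutated line (WT) and 3 of the derivative (MU). Per the submitters' processing notes, the genome build was mm10 and the tools were FastQC 0.11.4, HISAT2 2.05.0, featureCounts 1.5.0-p3 and DESeq2 1.20.0. The roles of these tools, the strand setting, the annotation version and the way TPM was computed are not given in the sources used here.

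The authors deposited a table of log2 values per gene and library, which per the file headers and the values themselves is log2(TPM + 1). TPM divides each gene's reads by transcript length and scales each library to the same total, so the deposited TPM values keep no sequencing depth. Depth is therefore unknown, and no counting interval or detection floor was computed. Values were kept to at most 4 digits, so the TPM of the most abundant genes comes in visible steps. The authors also deposited a table with a log2 fold change, a p-value and an adjusted p-value for each gene, and the mean TPM of each group. All columns of the expression table were matched to a labelled library by name.

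The values were returned to TPM and tested as log2(TPM + 1). Genes with a TPM of at least 1 in at least 3 of the 6 libraries were kept, which left 14209 genes. Differences between MU and WT were tested with limma 3.58.1 in R 4.3.3 (moderated, with an intensity trend, two-sided, no covariate). Calls are at a Benjamini-Hochberg adjusted p under 0.05. A fold change is a difference on the log2(TPM + 1) scale, which understates the change of genes with low TPM. A gene listed at 0 in all libraries of a group is given with its TPM per library and no fold, since a 0 in such a table does not show that the RNA was absent. Group values are mean ± SD of TPM over the 3 libraries of a group. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

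Genes were matched to GENCODE release M21 (GRCm38, the same assembly as mm10) by identifier, for 55141 of the 55401 genes. Positions, biotypes, GC content and exon lengths come from that release, and GC content and length were known for 99.9% of the tested genes.

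The comparison, the tests, the gene lists, the rule for naming genes and all settings not said otherwise were fixed before the data were examined. Genes are named by this rule: the 12 largest rises and the 12 largest falls among protein-coding genes that pass, do not overlap between groups and have a mean TPM of at least 5 in the higher group; Tars2, Cdkn1a, Gdf15 and Atf4; and, in each list, the 2 higher and the 2 lower members with the smallest adjusted p. Any other gene is said to have been chosen after its values were seen. A gene that the rule selects is not reported here. The 25 lists were mtDNA-encoded mRNAs, nuclear complex I, nuclear complexes II to V, mitochondrial ribosomal proteins, mitochondrial aminoacyl-tRNA synthetases, cytosolic aminoacyl-tRNA synthetases, mitochondrial transcription and translation factors, ATF4 and integrated stress response, mitochondrial chaperones and proteases, antioxidant and NRF2 targets, G1/S and DNA replication, G2/M and mitosis, G1 regulators, p53 targets, glycolysis, TCA cycle, fibrillar matrix and remodelling, contractile and SRF/YAP targets, interferon-stimulated genes, inflammatory cytokines and secretory factors, cholesterol synthesis, and markers of adipocytes, muscle, epithelium, and leukocytes and endothelium. Of their 668 members, 663 matched as written and 5 through an older symbol. Lists with at least 3 tested members were tested with camera (limma, preset correlation 0.01, two-sided), adjusted over 23 lists. Camera compares a list's members with all other genes, so its direction can differ from the sign of the list's median.

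The share of TPM from the 13 mtDNA-encoded mRNAs was compared with a two-sided exact permutation test. Alternatives were a replicate block, pseudocounts of 0.1 and 5, no filter, a TPM minimum of 5, rescaling without mtDNA-encoded genes, median-of-ratios scaling, quantile normalization, limma without trend or with robust estimation, leaving out each library in turn, camera with an estimated correlation, and fry. Added after seeing the data were a correction for GC content and length (loess, span 0.3) and a position-centred fit. The latter subtracted from the MU libraries the median fold change of up to 20 neighbouring protein-coding genes on each side. This median was taken relative to that of all tested genes. The mtDNA-encoded genes have no such neighbours and were left unchanged. A planned count test was not run because the tables used here give no counts.

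The test was tried on simulated data for the comparison of MU with WT, with 200 changed genes among 14209. It recovered 14.9% of genes changed by 0.5 on the log2 scale, 62.7% of those changed by 1 and 93.9% of those changed by 2. It made 5 calls among unchanged genes, and 0 calls when no change was planted. The changed genes were drawn from those at about 5 TPM or more in WT, while the test keeps genes from 1 TPM. In the real data 18.8% of genes passed, a larger part than was changed here, so these rates need not hold there. With 1 list shifted, 1 of 23 lists passed, and it was the shifted one. Noise was drawn separately for each gene and library, so members of a list were not correlated. This run thus cannot show how often correlated lists pass by mistake. In the other splits of the real libraries, described below, 1 to 4 lists passed. Each of those splits mixes WT and MU libraries unevenly and keeps part of the difference between the lines. Their numbers thus give no rate of mistaken passes either. A chromosome shift of −0.4 was read back as −0.39, and the GC correction brought a planted Spearman correlation of 0.76 to −0.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.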

Results

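Messenger RNA was profiled in NIH-3T3, a line of mouse embryonic fibroblasts grown in serum-containing medium, and in a mutated derivative of it. Of the 6 libraries, 3 came from the unmutated line (WT) and 3 from the derivative (MU). The comparison asks how the transcriptome of the mutated cells differs, in a study whose title concerns mitochondrial translation infidelity, oxidative stress and cell cycle arrest. The labels name neither the mutated gene nor the mutation, and do not say whether MU is a single clone. With a single unmutated line and a single derivative, effects of the mutation cannot be told apart from other differences between the lines. Sequencing depth is unknown because the values are in TPM. A TPM of at least 1 was reached by 14017.3 ± 61.5 genes in WT and 14072.3 ± 111.5 in MU (mean ± SD, n = 3, two-sided exact permutation p = 0.6).

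Correlations of log2(TPM + 1) were 0.949 to 0.966 among WT libraries, 0.971 to 0.976 among MU libraries and 0.937 to 0.945 between the groups (Pearson, across genes, which are not independent replicates). The first principal component held 45.4% of the variance and separated the groups, and the second held 22.1% and set WT replicate 2 apart from WT replicate 3. These WT libraries also lay at opposite ends in their dependence on GC content. The Spearman correlation of a library's deviations with GC was 0.38 for WT replicate 2, −0.31 for WT replicate 3 and 0.21 for MU replicate 3. It lay between −0.13 and −0.08 for the other libraries.

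In the mutated cells, genes of smooth-muscle actins, fibrillar matrix genes (14 of 30, with 6 lower) and some p53 targets (6 of 20) rose. Many genes of DNA replication (25 of 45) and those of glutathione reductase and several chemokines fell. Of 23 gene lists tested, 7 passed camera, and 0 passed with an estimated correlation. That form of camera is limited to the 4 residual degrees of freedom, so it has little power with 3 libraries per group. The estimated correlation was below the preset 0.01 for p53 targets (0.000505), antioxidant genes (−0.0137) and inflammatory genes (−0.0327). Correlated members thus do not account for the loss of these calls. In the other passing lists it was 0.0277 to 0.636. Of 14209 genes tested, 2667 passed at an adjusted p under 0.05 (limma), 1012 higher and 1655 lower in MU. Without adjustment, 4741 had a p under 0.05 (limma). Among protein-coding genes 2431 of 11358 passed, 863 higher and 1568 lower. A change of at least 2-fold was found in 712 genes, 330 higher and 382 lower. Values of the groups did not overlap in 5569 genes, 39.2% of those tested, where chance gives 10%. The share of calls that were higher in MU was 37.9%. This split depended on scaling, since 48.6% were higher after rescaling without mtDNA-encoded genes, 46.2% with median-of-ratios scaling and 48.8% with quantile normalization. The number of genes passing was 1430 without WT replicate 1, 1158 without MU replicate 1, 1071 without MU replicate 2 and 1203 without MU replicate 3.

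The largest rise was in Vip (ENSMUSG00000019772.5, chromosome 10, 5639218 to 5647617, GRCm38), which encodes the neuropeptide vasoactive intestinal peptide. Its level went from 0.348 ± 0.164 TPM in WT to 112 ± 9.38 TPM in MU, a log2 fold change of 6.40 (SE 0.13, limma adjusted p = 1.32e-05). Smooth-muscle actins followed. Actg2 (ENSMUSG00000059430.14, chromosome 6, 83512905 to 83536265) rose from 0.955 ± 0.445 to 82.4 ± 7.14 TPM, by 5.44 on the log2 scale. Acta2 (ENSMUSG00000035783.9, chromosome 19, 34241090 to 34255590) rose from 143 ± 23.7 to 977 ± 40.8 TPM, by 2.78. Among genes of secreted proteins, Spon2 rose from 11.7 ± 1.29 to 139 ± 11.3 TPM, and Mfap5, a component of elastic microfibrils, from 4.22 ± 1.47 to 34.2 ± 4.19 TPM. Cbr2, a carbonyl reductase, went from 6.56 ± 0.705 to 125 ± 21.9 TPM. Akr1c13, an aldo-keto reductase, went from 0.372 ± 0.299 to 8.76 ± 0.083 TPM, and Gstm2, a glutathione transferase, from 7.86 ± 2.91 to 53.7 ± 2.44 TPM. Aqp5, a water channel, rose from 4.86 ± 1.33 to 53.6 ± 7.50 TPM. AU021092 rose from 2.03 ± 0.408 to 32.1 ± 2.23 TPM and Pnma5 from 0.263 ± 0.0878 to 15.8 ± 1.01 TPM. Rhox2h, a reproductive homeobox gene, was at 10.9 ± 1.89 TPM in MU and at 0.0425 ± 0.0736 TPM in WT. The values of Rhox2h, Akr1c13 and Gstm2 are uncertain, because close paralogs lie beside them and could share reads.

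Among the largest falls, Crtap, Hs6st2 and Gm1673 were listed at 0 in all MU libraries. Crtap (ENSMUSG00000032431.6, chromosome 9, 114375134 to 114390675) encodes a protein of the complex that hydroxylates collagen prolines, and stood at 16.8, 16.96 and 17.5 TPM in the WT libraries. Hs6st2, a heparan sulfate sulfotransferase, stood at 18.9, 14.9 and 20.6 TPM in WT, and Gm1673 at 26.7, 24.1 and 12.3 TPM. In all, 7 protein-coding genes with a mean of at least 5 TPM in WT were listed at 0 in MU, and 0 were in the reverse direction. Over genes of all kinds these numbers were 9 and 6. Dcn (ENSMUSG00000019929.16, chromosome 10, 97479609 to 97518143), which encodes the collagen-binding proteoglycan decorin, fell from 119 ± 19.7 to 8.13 ± 0.704 TPM, a log2 fold change of −3.71 (SE 0.14, limma adjusted p = 7.8e-05). Agtr2, the type 2 angiotensin II receptor, fell from 24.0 ± 8.30 to 0.367 ± 0.0565 TPM. Both a neuronal beta-tubulin gene, Tubb3, and an alpha-tubulin gene, Tuba4a, fell, from 14.9 ± 0.983 to 0.0436 ± 0.0755 TPM and from 10.9 ± 1.84 to 0.0771 ± 0.134 TPM. Dkk2, a secreted modulator of Wnt signalling, fell from 10.6 ± 0.952 to 0.0525 ± 0.0267 TPM. Rgs16, a regulator of G protein signalling, fell from 39.2 ± 9.19 to 1.89 ± 0.292 TPM. Cthrc1 fell from 12.7 ± 2.82 to 0.0650 ± 0.113 TPM and AW551984 from 10.5 ± 3.55 to 0.0359 ± 0.0622 TPM. For AW551984 the authors' deposited table gives a log2 fold change of −1.46 and no adjusted p, against −3.43 in limma. Evi2a fell from 15.8 ± 0.0533 to 0.486 ± 0.201 TPM. It lies inside Nf1 on the other strand, and the strand setting of the counting is not given in the sources used here.

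**Figure D1:**
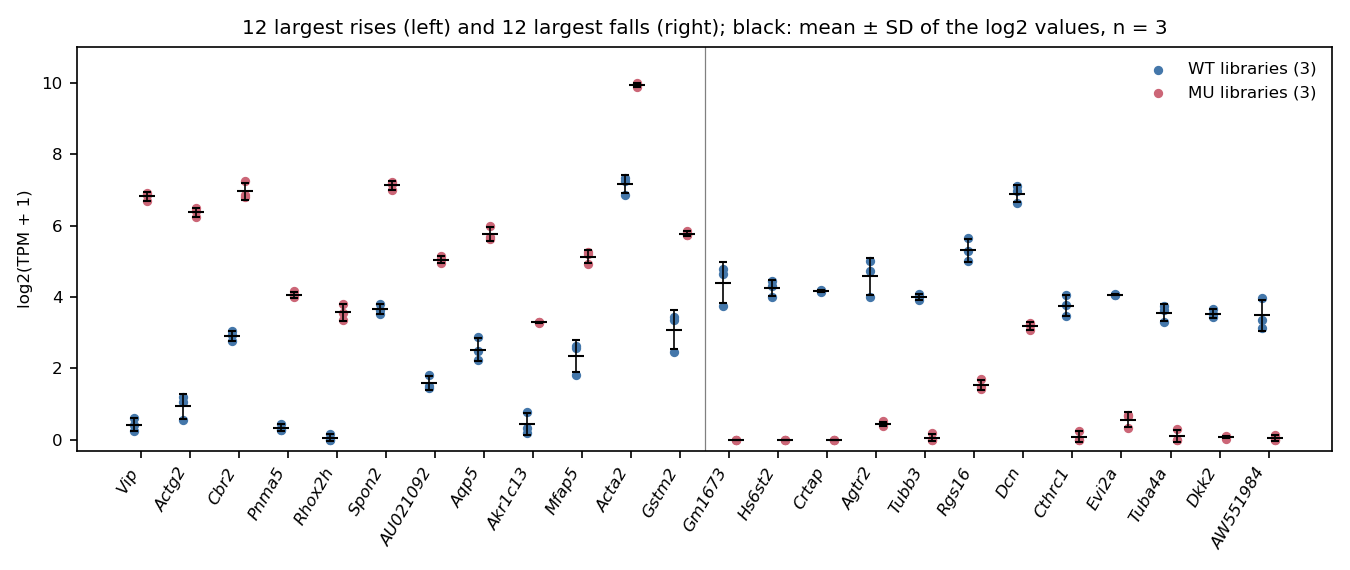
Points show log2(TPM + 1) of each library for the 12 largest rises and the 12 largest falls, blue for WT and red for MU, with black bars for the mean ± SD of 3 libraries. The groups do not overlap in any of these genes, and Crtap, Hs6st2 and Gm1673 lie at 0 in all MU libraries.

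Tars2 (ENSMUSG00000028107.14, chromosome 3, 95739976 to 95760206) encodes mitochondrial threonyl-tRNA synthetase, the enzyme that the published study of this title concerns. Its mRNA was at 57.7 ± 4.53 TPM in WT and 45.3 ± 3.54 TPM in MU, a log2 fold change of −0.34 (SE 0.10) that did not pass over all genes (limma adjusted p = 0.057). Without WT replicate 2 it passed, at an adjusted p of 0.0365 (limma). As the labels do not name the mutated gene, this level is no check of them. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 62.3 ± 3.62 TPM in WT and 75.7 ± 3.62 TPM in MU, with a log2 fold change of 0.28 (SE 0.08, limma adjusted p = 0.0643). It passed without WT replicate 2 (adjusted p = 0.0272, limma), after rescaling without mtDNA-encoded genes (0.0323) and with quantile normalization (0.0289). Atf4, a transcription factor of the integrated stress response, was at 417 ± 68.4 TPM in WT and 377 ± 16.3 TPM in MU (limma adjusted p = 0.557), with a log2 fold change of −0.13 that became 0.0144 with quantile normalization (adjusted p = 0.961). Gdf15, a secreted marker of mitochondrial stress, stayed at or below 0.181 TPM in every library and was not tested.

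Transcripts of mtDNA took a larger share of TPM in every MU library than in any WT library. The 13 mtDNA-encoded mRNAs made up 10.7% ± 1.96 of TPM in WT and 14.6% ± 0.753 in MU (mean ± SD, n = 3). The difference was 3.98 percentage points, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. Of the 13, 12 had a higher mean in MU, and 2 rose past the threshold, or 3 when adjusted over the list alone. These were mt-Nd4l, from 7335.3 ± 1902.8 to 13690.0 ± 1278.7 TPM (log2 fold change 0.93, limma adjusted p = 0.0313), and mt-Atp6, from 12921.9 ± 2738.0 to 22088.9 ± 1045.7 TPM (0.79, adjusted p = 0.0428). Each overlaps a neighbouring mtDNA gene, mt-Nd4 or mt-Atp8. The level of mt-Nd1 was 9221.8 ± 1187.3 TPM in WT and 9117.5 ± 460.1 TPM in MU. The list passed camera as higher in MU (adjusted p = 0.00549), and its adjusted p = 0.59 with an estimated correlation. The list did not pass without WT replicate 2 (adjusted p = 0.0637) or with quantile normalization (0.564). Quantile normalization gives all libraries the same set of values, so it removes by construction part of a rise shared by the most abundant genes. The 10 most abundant genes made up 10.4% of TPM in WT and 14.3% in MU, close to the shares of the 13 mRNAs. No single mRNA of the 13 passed with quantile normalization, or without WT replicate 1 or any 1 of the MU libraries, and 4 passed without WT replicate 3.

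**Figure D2:**
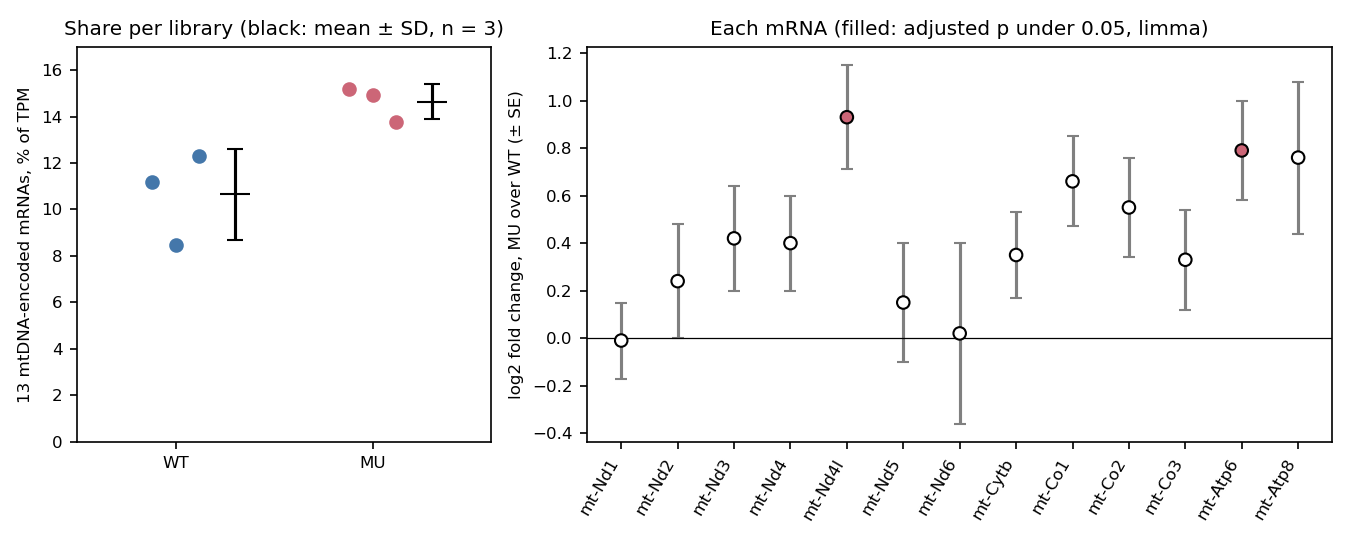
Left, percent of TPM from the 13 mtDNA-encoded mRNAs in each library, with the mean ± SD of 3 libraries in black. The MU libraries lie at 13.8% to 15.2% and the WT libraries at 8.48% to 12.3%. Right, log2 fold change (MU over WT) ± SE of each mRNA, filled for mt-Nd4l and mt-Atp6, which passed an adjusted p under 0.05 (limma).

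Few nuclear genes of oxidative phosphorylation passed. Of 37 tested complex I genes, 0 passed in either direction (limma) and 0 when adjusted over the list alone. Ndufa6 was at 115 ± 13.96 TPM in WT and 148 ± 10.0 TPM in MU (adjusted p = 0.065, limma), and Ndufa2 at 183 ± 35.9 and 135 ± 14.97 TPM (0.118). Ndufa6 passed without WT replicate 2 (limma adjusted p = 0.0212), after rescaling without mtDNA-encoded genes (0.0357) and with quantile normalization (0.0354). In this list 2 genes passed as higher and 1 as lower without WT replicate 2, and 1 as lower without WT replicate 3. Passing as higher were 1 after rescaling without mtDNA-encoded genes, 3 with quantile normalization and 1 after position centring. With the GC and length correction, Ndufa6 passed as higher (limma adjusted p = 0.0295), and Ndufa2 (0.038) and Ndufc2 (0.0466) as lower. Of 40 genes of complexes II to V, 5 fell and 0 rose (0 when adjusted over the list alone). Atp5pb fell from 217 ± 8.04 to 161 ± 9.80 TPM, and 2 of the 5 fallen genes lay on chromosomes whose genes were lower as a whole. Atp5pb did not pass without WT replicate 1 (limma adjusted p = 0.0557), any 1 MU library (0.0625 to 0.0751) or with quantile normalization (0.0544). The falls in this list numbered 1 without WT replicate 1 or 3 and 0 without any 1 MU library. Rises numbered 1 without WT replicate 2 and 3 without WT replicate 3. Of the 40 genes, 1 fell after rescaling without mtDNA-encoded genes, 3 with median-of-ratios scaling, 0 with quantile normalization (where 2 rose) and 3 after position centring, which ended the call of Atp5pb (0.0739). The lists' camera adjusted p were 0.551 and 0.963 (0.649 and 0.969 with an estimated correlation). Their medians were −0.03 and −0.02 while camera read them as higher than other genes, and both medians were above 0 with each of the other scalings.

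Genes of mitochondrial protein synthesis gave a mixed picture. Of 76 mitochondrial ribosomal protein genes, 2 rose and 10 fell (1 and 4 when adjusted over the list alone), with a median log2 fold change of −0.19 and a camera adjusted p of 0.0603 (0.419 with an estimated correlation). Mrpl36 fell from 66.2 ± 6.01 to 37.3 ± 1.09 TPM and Mrpl30 rose from 199 ± 7.23 to 277 ± 4.07 TPM. This list passed without WT replicate 1 (adjusted p = 0.0301), without WT replicate 3 (0.0238) and without MU replicate 3 (0.0396). It also passed with no filter (0.00229), with the GC and length correction (0.0391) and after position centring (0.0236). Its fallen members numbered 4 with each other scaling, and after position centring 1 rose and 3 fell. Of 26 mitochondrial transcription and translation factors, Mtif2, an initiation factor, rose from 14.9 ± 0.368 to 31.1 ± 4.92 TPM. Gfm1, an elongation factor, fell from 112 ± 9.77 to 68.6 ± 3.77 TPM, and Tsfm from 61.0 ± 2.07 to 49.0 ± 0.386 TPM (1 higher and 2 lower in both counts, camera adjusted p = 0.626, 0.804 with an estimated correlation). Among 17 mitochondrial aminoacyl-tRNA synthetases, Yars2 fell from 43.3 ± 3.25 to 28.7 ± 2.00 TPM and Cars2 from 21.5 ± 0.870 to 16.6 ± 0.980 TPM, and 0 rose (1 fall when adjusted over the list alone, camera adjusted p = 0.907, 0.949 with an estimated correlation). Cars2 lies on chromosome 8, where 83.1% of genes had a lower mean in MU, and its log2 fold change was 0.06 after position centring. Of 21 cytosolic synthetases, 1 rose (Eprs, from 80.4 ± 5.63 to 117 ± 0.330 TPM) and 4 fell, 3 of them on chromosomes with lowered medians (1 and 5 when adjusted over the list alone, camera adjusted p = 0.48, 0.649 with an estimated correlation). Farsa fell from 87.3 ± 3.18 to 59.5 ± 4.83 TPM. Of 16 mitochondrial chaperones and proteases, Afg3l2 fell from 48.7 ± 2.51 to 31.1 ± 1.23 TPM and Hspa9 from 463 ± 27.0 to 365 ± 4.00 TPM. Both lie on chromosome 18, and 0 members rose (the same counts when adjusted over the list alone, camera adjusted p = 0.24, 0.425 with an estimated correlation). Without WT replicate 1 or any 1 MU library, the fallen members numbered 1 or 2 among ribosomal proteins, 0 or 1 among mitochondrial synthetases and 0 to 2 among cytosolic ones. They numbered 1 among factors and 1 among chaperones, and 1 ribosomal protein gene passed as higher. Without WT replicate 3, 4 chaperone genes passed as lower, and 2 factors and 1 mitochondrial synthetase as higher. Yars2 and Farsa did not pass without MU replicate 2 (limma adjusted p = 0.0547 and 0.0533), and Cars2 did not pass without any 1 of the 6 libraries (0.0522 to 0.152). Tsfm and Hspa9 did not pass without WT replicate 1 (0.066 and 0.0956) or any 1 MU library (0.118 to 0.124 and 0.125 to 0.143). Cars2, Tsfm and Hspa9 also did not pass after rescaling without mtDNA-encoded genes (0.0784, 0.0722 and 0.0917). Position centring ended the calls of Eprs (0.0584), Farsa (0.0961) and Hspa9 (0.146), and left 1 fall and 0 rises among cytosolic synthetases. With median-of-ratios scaling or quantile normalization, 1 cytosolic synthetase fell, 1 mitochondrial synthetase rose and 1 fell, and 2 factors rose and 1 fell. Among chaperones, 1 fell after rescaling without mtDNA-encoded genes or with quantile normalization. The same rescaling left 1 fall each among mitochondrial synthetases and factors.

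Antioxidant genes fell more often than they rose. Of 36 antioxidant and NRF2 target genes tested, 12 fell and 4 rose (13 and 5 when adjusted over the list alone), with a median log2 fold change of −0.21. Gsr, which encodes glutathione reductase, fell from 136 ± 5.31 to 59.6 ± 3.42 TPM (log2 fold change −1.17, limma adjusted p = 0.000535). Gpx7, an endoplasmic reticulum peroxidase, was at 9.13, 5.90 and 7.89 TPM in WT and listed at 0 in all MU libraries. Chosen after their values were seen, Gclm, a subunit of the enzyme that begins glutathione synthesis, changed by −1.28 on the log2 scale (SE 0.11), Hmox1 by −1.24 (SE 0.22) and Txnrd1 by −0.64 (SE 0.08). In the other direction, the glutathione transferase Gsta4 rose from 78.0 ± 0.571 to 137 ± 3.69 TPM and Gss, glutathione synthetase, from 19.02 ± 1.49 to 25.6 ± 2.08 TPM. Gss did not pass without WT replicate 1 (limma adjusted p = 0.0944), WT replicate 3 (0.0767) or any 1 MU library (0.0782 to 0.139), nor after position centring (0.0814), where 2 members rose. Of the 12 fallen genes, 4, among them Gsr, Gclm and Hmox1, lay on chromosomes with lowered medians. As a whole the list passed camera as lower in MU (adjusted p = 0.0282), and its adjusted p = 0.206 with an estimated correlation. It did not pass without WT replicate 2 (adjusted p = 0.0684), with a TPM minimum of 5 (0.0524) or with quantile normalization (0.126). The rising members numbered 1 without WT replicate 1 or any 1 MU library, and 2 without WT replicate 3.

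The ATF4 and integrated stress response list went both ways, with a balance that depended on scaling. Of 29 genes, 5 rose and 5 fell (6 and 5 when adjusted over the list alone, camera adjusted p = 0.963, 0.969 with an estimated correlation). The amino acid transporter gene Slc1a4 rose from 31.7 ± 1.37 to 48.6 ± 0.278 TPM, and Aldh1l2, of mitochondrial folate metabolism, from 56.4 ± 1.75 to 80.6 ± 1.56 TPM. Mthfd2, an enzyme of the same pathway, fell from 122 ± 9.35 to 91.2 ± 4.44 TPM, and Phgdh, of serine synthesis, from 358 ± 29.2 to 268 ± 11.6 TPM. Ddit3 and Trib3, chosen after their values were seen, changed by 0.73 (SE 0.16) and 0.61 (SE 0.13) on the log2 scale. The list's median was −0.13 and its mean −0.04, while camera placed it above other genes. Without WT replicate 1 or any 1 MU library, 2 members passed as higher and 0 as lower. In these settings limma gave an adjusted p of 0.075 to 0.102 for Mthfd2, 0.0776 to 0.117 for Phgdh, 0.0665 to 0.0853 for Ddit3 and 0.0593 to 0.0739 for Trib3. Members rising and falling numbered 6 and 2 after rescaling without mtDNA-encoded genes, 5 and 3 with median-of-ratios scaling and 5 and 2 with quantile normalization. Mthfd2 did not pass in the first (0.0567) and the last of these (0.0616), nor Phgdh with median-of-ratios scaling (0.0566) or quantile normalization (0.139). Of the 5 fallen members 3 lay on chromosomes with lowered medians. Position centring left 4 rises and 2 falls and ended the calls of Phgdh (0.291) and Ddit3 (0.0803).

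Many genes of DNA replication fell. Of 45 G1/S and DNA replication genes, 25 fell and 0 rose (33 and 0 when adjusted over the list alone), 42 had a lower mean in MU, and the median log2 fold change was −0.44. Rrm2, a subunit of ribonucleotide reductase, fell from 157 ± 11.99 to 74.3 ± 4.41 TPM (log2 fold change −1.07, SE 0.09, limma adjusted p = 0.00124). Mcm5, a subunit of the replicative helicase, fell from 148 ± 7.51 to 81.1 ± 2.50 TPM (−0.86, SE 0.08, adjusted p = 0.00138). Chosen after their values were seen, Ccne1, encoding cyclin E1, changed by −0.94 (SE 0.11), Tk1 by −0.78 (SE 0.08) and Pcna by −0.42 (SE 0.09) on the log2 scale. Pcna did not pass without WT replicate 1 (limma adjusted p = 0.0685), any 1 MU library (0.0643 to 0.0975), after rescaling without mtDNA-encoded genes (0.059) or with quantile normalization (0.086). The members with the smallest adjusted p among those higher, Prim2 (27.8 ± 1.82 and 31.6 ± 1.02 TPM) and Rfc4 (61.2 ± 22.2 and 65.0 ± 4.63 TPM), did not pass. The list passed camera as lower in MU (adjusted p = 1.94e-09), and its adjusted p = 0.147 with an estimated correlation. On the chromosomes with lowered medians lay 16 of the 45 tested and 10 of the 25 fallen genes, among them Mcm5. The fallen genes numbered 12 without WT replicate 1, 8 without MU replicate 1, 10 without MU replicate 2 and 12 without MU replicate 3. They numbered 16 to 19 with the other scalings and 16 after position centring.

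Of 44 G2/M and mitosis genes, 5 fell and 3 rose, also when adjusted over the list alone (median −0.15, camera adjusted p = 0.135, 0.633 with an estimated correlation). Kif4 fell from 26.6 ± 1.38 to 15.4 ± 0.657 TPM and Cenpa from 210 ± 32.4 to 129 ± 1.79 TPM, and both lie on chromosomes with lowered medians, as did 3 of the 5. Racgap1 rose from 153 ± 15.2 to 199 ± 3.97 TPM and Nusap1 from 29.2 ± 3.30 to 39.3 ± 1.75 TPM. The fallen members numbered 2 without WT replicate 1, 12 without WT replicate 2 and 1 without any 1 MU library. The risen members numbered 1 without WT replicate 3 and 0 without any 1 MU library. The balance depended on scaling, with 3 rises and 2 falls after rescaling without mtDNA-encoded genes, 4 and 5 with median-of-ratios scaling and 5 and 2 with quantile normalization. The list passed with no filter (adjusted p = 0.0106). Cenpa did not pass without any 1 MU library (limma adjusted p of 0.0538 to 0.0558). Racgap1 did not pass without WT replicate 3 (0.059) or any 1 MU library (0.108 to 0.132). Nusap1 did not pass without WT replicate 1 (0.0552), WT replicate 3 (0.0549) or any 1 MU library (0.107 to 0.138). Position centring left 1 rise and 5 falls and ended the calls of Cenpa (0.192) and Racgap1 (0.208). Of 14 G1 regulators, Rb1 rose from 7.45 ± 1.36 to 12.6 ± 0.461 TPM, while Cdk6 fell from 19.2 ± 1.71 to 11.95 ± 1.10 TPM and Ccnd1, encoding cyclin D1, from 165 ± 24.1 to 122 ± 2.90 TPM (2 higher and 2 lower when adjusted over the list alone). This list's camera adjusted p was 0.963, and 0.969 with an estimated correlation. Camera placed it above other genes, although its median was −0.01, and above 0 with each other scaling. Of these genes, Rb1 did not pass without WT replicate 1 or any 1 MU library (limma adjusted p of 0.0635 to 0.0817). Cdk6 did not pass without MU replicate 2 (0.0505) or MU replicate 3 (0.0521). Ccnd1 did not pass without WT replicate 1 (0.0932), any 1 MU library (0.124 to 0.155) or with any other scaling (0.0591 to 0.12). After position centring 0 G1 regulators passed (0.22 for Rb1, 0.0872 for Cdk6 and 0.0626 for Ccnd1). Rises and falls among them numbered 2 and 1 after rescaling without mtDNA-encoded genes or with quantile normalization, and 1 each with median-of-ratios scaling. The inhibitors Cdkn2a and Cdkn2b, chosen after their values were seen, were listed at 0 in all 6 libraries.

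Some targets of p53 rose. Of 20 tested, 6 rose and 0 fell (8 and 1 when adjusted over the list alone), with a median log2 fold change of 0.29. Trp53inp1 rose from 5.95 ± 0.530 to 17.8 ± 2.12 TPM (log2 fold change 1.43, SE 0.13, limma adjusted p = 0.00132), and Plk2, a stress-responsive kinase gene, from 65.0 ± 4.69 to 140 ± 2.04 TPM (1.10, SE 0.08, adjusted p = 0.000705). The others that passed were Ccng1, Ddb2, Polk and Tnfrsf10b, named after their values were seen, and Polk did not pass without any 1 of the 6 libraries (limma adjusted p of 0.0622 to 0.157). Aen was at 66.5 ± 17.8 TPM in WT and 41.3 ± 2.74 TPM in MU (adjusted p = 0.0515, limma). The list passed camera as higher in MU (adjusted p = 0.000606), and its adjusted p = 0.147 with an estimated correlation. Members passing as higher numbered 3 without WT replicate 1 and 2 without any 1 MU library, where Plk2 and Trp53inp1 alone kept their calls. After position centring 4 members rose, and Ccng1 (0.0592) and Tnfrsf10b (0.186) did not pass. Aen passed as lower without WT replicate 2 (limma adjusted p = 0.0185) or WT replicate 3 (0.0428). It also passed as lower with a TPM minimum of 5 (0.0417) and with the GC and length correction (0.0311).

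Many contractile genes rose. Of 18 contractile and SRF/YAP target genes, 10 rose and 1 fell (13 and 1 when adjusted over the list alone), 17 had a higher mean in MU, and the median log2 fold change was 0.64. Besides Actg2 and Acta2, the genes Myl9, Amotl2, Tgfb1i1, Tagln and Tpm1, named after their values were seen, changed by 1.53, 1.44, 1.42, 1.29 and 1.26 on the log2 scale. Ccn2, a secreted protein gene driven by YAP, fell from 109 ± 9.74 to 81.7 ± 2.36 TPM. Ccn2 did not pass without WT replicate 1 (limma adjusted p = 0.0664) or any 1 MU library (0.0806 to 0.107), and Tagln not without MU replicate 1 (0.0552) or MU replicate 2 (0.0569). Ccn2 also did not pass after rescaling without mtDNA-encoded genes (0.0573) or with quantile normalization (0.0687). Camera read the list as higher in MU (adjusted p = 1.2e-09), and its adjusted p = 0.195 with an estimated correlation.

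Fibrillar matrix genes changed in both directions with more rises. Of 30 tested, 14 rose and 6 fell (16 and 6 when adjusted over the list alone), with a median log2 fold change of 0.33. Thbs1, encoding thrombospondin 1, rose from 55.0 ± 2.72 to 206 ± 3.33 TPM (1.88, SE 0.08, limma adjusted p = 8.17e-05). Col5a2, a chain of type V collagen, rose from 47.9 ± 2.63 to 128 ± 2.55 TPM. The chains of type I collagen, chosen after their values were seen, changed by 1.34 (Col1a2, SE 0.10) and 0.91 (Col1a1, SE 0.10) on the log2 scale, and Fn1, fibronectin, by 0.96 (SE 0.12). Besides Dcn, Thbs2, encoding thrombospondin 2, fell from 64.8 ± 0.432 to 33.3 ± 1.08 TPM. The list passed camera as higher in MU (adjusted p = 0.00145), and its adjusted p = 0.214 with an estimated correlation. Members passing as higher numbered 8 without MU replicate 2 and 9 without MU replicate 3.

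Several secreted inflammatory factors fell. Of 16 tested, 6 fell and 1 rose (7 and 4 when adjusted over the list alone), with a median log2 fold change of −0.39. Cxcl12, a chemokine gene, fell from 16.96 ± 0.903 to 0.964 ± 0.0742 TPM (−3.19, SE 0.12, limma adjusted p = 7.8e-05), and Hgf, hepatocyte growth factor, from 24.6 ± 2.10 to 3.64 ± 0.536 TPM. The others that fell, named after their values were seen, were Cxcl5, Igfbp7, Ccl2 and Cxcl1. Csf1, a macrophage growth factor gene, rose from 112 ± 2.59 to 174 ± 1.18 TPM. Il6 was at 0.691 ± 0.216 TPM in WT and 1.62 ± 0.159 TPM in MU (adjusted p = 0.0689, limma). On chromosome 5, whose median was lowered, lay 4 of the 6 fallen genes. Of the 16 tested, 7 lay on chromosomes with lowered medians, among them the risen Csf1. The median of chromosome 5, −0.26, was small beside the log2 fold change of Hgf there (−2.47). The list passed camera as lower in MU (adjusted p = 0.0327), and its adjusted p = 0.214 with an estimated correlation. It did not pass without WT replicate 2 (adjusted p = 0.0929). The risen members numbered 2 without WT replicate 2 or WT replicate 3, after rescaling without mtDNA-encoded genes, with quantile normalization and after position centring, where Il6 passed (0.015).

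Of 14 interferon-stimulated genes, 4 rose and 2 fell (6 and 3 when adjusted over the list alone), with a median of 0.42 and a camera adjusted p of 0.0662 (0.221 with an estimated correlation). Stat2 rose from 11.5 ± 0.681 to 20.6 ± 1.08 TPM and Bst2 from 9.81 ± 1.73 to 18.1 ± 1.88 TPM, while Ifit2 fell from 26.8 ± 1.41 to 13.1 ± 0.575 TPM and Ifit3 from 1.56 ± 0.204 to 0.461 ± 0.281 TPM. Members passing as higher numbered 2 without WT replicate 1, 1 without MU replicate 1, 2 without MU replicate 2 and 1 without MU replicate 3. Without any 1 of the 6 libraries, 1 member passed as lower, and Ifit3 did not pass (limma adjusted p of 0.0617 to 0.145) nor with any other scaling (0.0506 to 0.0585). Bst2 did not pass without MU replicate 1 (0.061) or MU replicate 3 (0.058). The fallen members numbered 1 with each other scaling, and the list passed with a TPM minimum of 5 (adjusted p = 0.0466).

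In glycolysis, 6 of 21 genes fell and 0 rose (7 and 1 when adjusted over the list alone), with a median of −0.35 and a camera adjusted p of 0.0881 (0.549 with an estimated correlation). Pgk1 fell from 1004.5 ± 53.8 to 512 ± 8.43 TPM, and Pgam1 from 771 ± 66.4 to 462 ± 14.9 TPM. Pgk1 lies on the X chromosome, where its neighbours had a median log2 fold change of −0.59 relative to the median of all tested genes. The fallen members numbered 3 without any 1 MU library, 2 members passed as higher without WT replicate 2 and 1 after rescaling without mtDNA-encoded genes, and the list passed without WT replicate 3 (adjusted p = 0.0219) and with no filter (0.0232). Among 18 TCA cycle genes, Fh1 rose from 62.6 ± 6.33 to 82.8 ± 3.55 TPM and Sucla2 from 39.4 ± 0.544 to 50.1 ± 2.60 TPM. In the same list 3 fell, among them Pdha1, from 98.3 ± 3.89 to 69.7 ± 3.42 TPM, and Mdh2, from 403 ± 16.97 to 302 ± 4.09 TPM, both on chromosomes with lowered medians (2 and 4 when adjusted over the list alone, camera adjusted p = 0.626, 0.721 with an estimated correlation). Without WT replicate 1 or any 1 MU library, 0 members of the TCA list passed as higher and 0 to 2 as lower, and 6 passed as lower without WT replicate 2. Without WT replicate 3, 1 passed as higher. Fh1 did not pass without WT replicate 1 (limma adjusted p = 0.0528) or any 1 MU library (0.102 to 0.132). Sucla2 did not pass without WT replicate 1 (0.0752), WT replicate 3 (0.0515) or any 1 MU library (0.0793 to 0.122). After position centring, the log2 fold change was −0.07 for Sucla2 (limma adjusted p = 0.637) and 0.20 for Fh1 (0.231). It was −0.01 for Pdha1 (0.941) and −0.24 for Mdh2 (0.0895), and 0 TCA genes rose and 1 fell in that fit. Falls numbered 2 with each other scaling. Mdh2 did not pass without any 1 MU library (0.0654 to 0.0809), nor Pdha1 without MU replicate 2 (0.0512). Of 22 cholesterol synthesis genes, 3 rose and 1 fell (5 and 1 when adjusted over the list alone), with a camera adjusted p of 0.0666 (0.221 with an estimated correlation). Hmgcs1 rose from 132 ± 20.1 to 218 ± 7.35 TPM and Sqle from 175 ± 13.6 to 231 ± 3.41 TPM. The cholesterol genes passing as higher numbered 2 without WT replicate 1, 0 without MU replicate 1 or 2 and 1 without MU replicate 3, and 2 passed as lower without WT replicate 2. Hmgcs1 did not pass without MU replicate 1 (limma adjusted p = 0.051) or MU replicate 2 (0.055). Sqle did not pass without WT replicate 1 (0.0648) or any 1 MU library (0.0934 to 0.0967). With median-of-ratios scaling or quantile normalization 5 members rose. The list passed without WT replicate 2 (adjusted p = 0.047), with median-of-ratios scaling (0.0435), with quantile normalization (0.0113), with the GC and length correction (0.0389) and after position centring (0.0317).

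Most markers of other cell types were too low to be tested. Of 12 adipocyte markers, only Lpl was tested, and it fell from 20.7 ± 2.06 to 12.2 ± 0.379 TPM. Of 14 muscle markers, 4 were tested. Acta1, skeletal actin, rose from 0.658 ± 0.0616 to 3.004 ± 0.325 TPM and Myl4 fell from 3.06 ± 0.166 to 0.903 ± 0.696 TPM, while Tnnt2 was at 1.92 ± 1.23 and 3.99 ± 0.743 TPM (adjusted p = 0.103, limma). Of 11 epithelial markers, only Krt14 was tested, at 0.785 ± 0.265 TPM in WT and 1.49 ± 0.258 TPM in MU (adjusted p = 0.164, limma). Of 14 leukocyte and endothelial markers, 3 were tested. Csf1r rose from 1.87 ± 0.1095 to 5.34 ± 0.848 TPM, Cdh5 fell from 1.82 ± 0.861 to 0.105 ± 0.0118 TPM, and Cd68 was at 2.56 ± 0.721 and 4.47 ± 1.34 TPM (adjusted p = 0.147, limma). Camera gave adjusted p of 0.37 for muscle and 0.48 for leukocyte and endothelial markers (0.633 for each with an estimated correlation). Adjusted over the list alone, the counts of higher and lower members were 2 and 1 for each of these lists, 0 and 1 for adipocyte and 0 and 0 for epithelial markers. Myl4 did not pass without any 1 library except MU replicate 2 (limma adjusted p of 0.0597 to 0.103) or after position centring (0.0506), nor Cdh5 without any 1 MU library (0.0626 to 0.0653). Tnnt2 passed as higher without WT replicate 2 (0.0135).

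**Figure D3:**
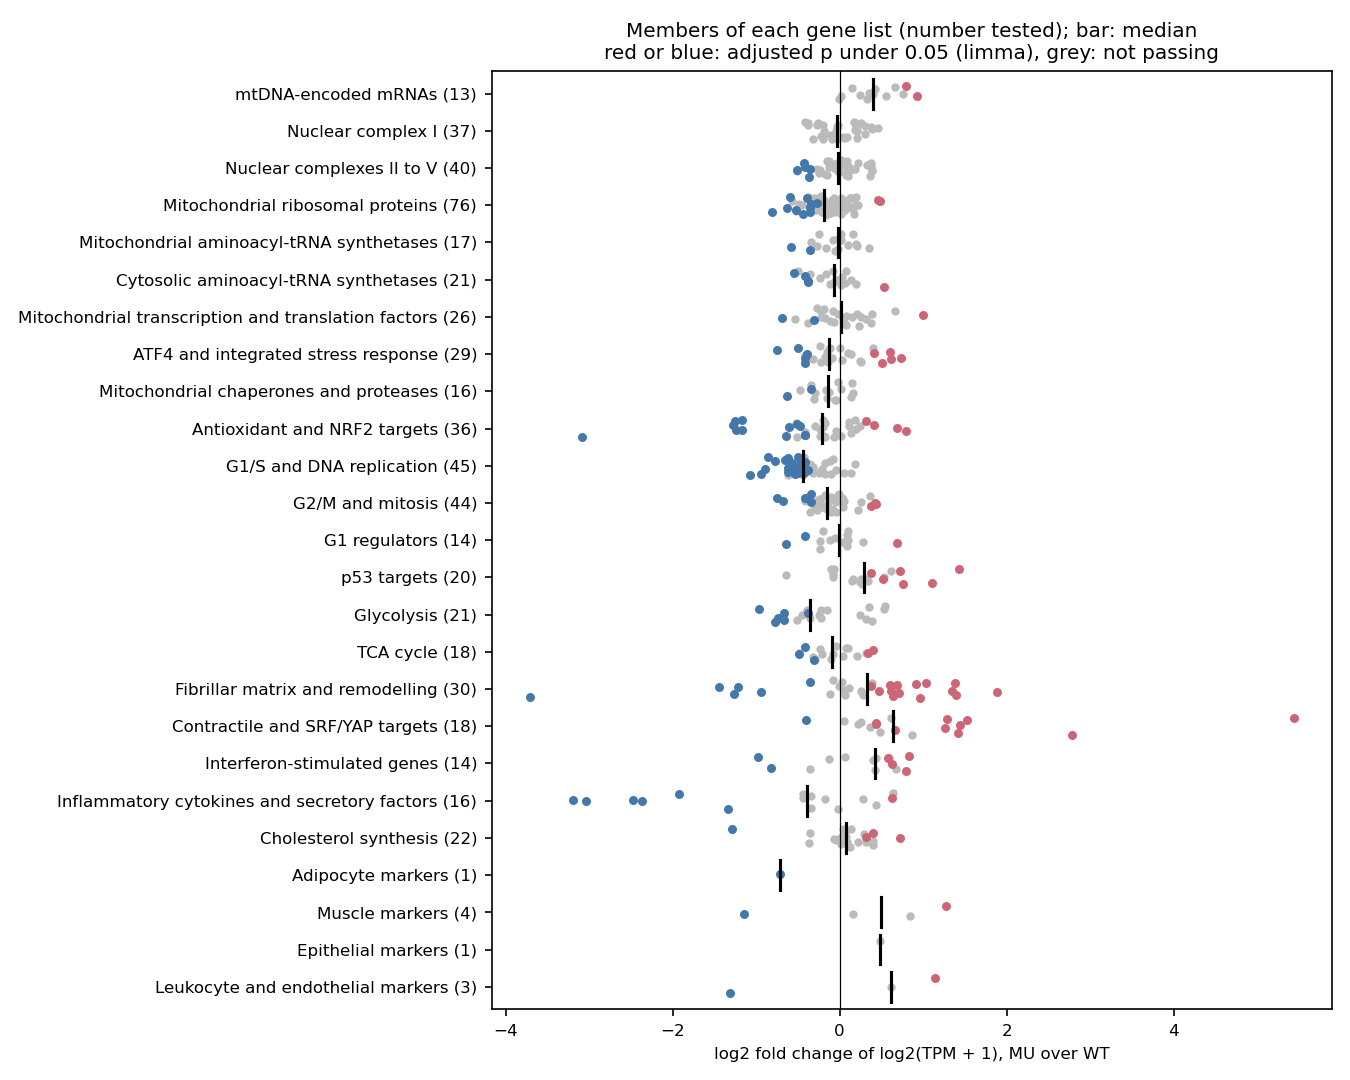
Each point is 1 tested gene of the list named on the left, placed by its log2 fold change of log2(TPM + 1), MU over WT; the number tested stands in brackets and the black bar is the median. Red and blue points passed an adjusted p under 0.05 (limma) as higher and lower. The DNA replication list lies to the left of 0, with a median of −0.44, and the contractile list to the right, with a median of 0.64.

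Fold changes differed by chromosome. Among 9443 protein-coding genes with a mean TPM of at least 5, the median log2 fold change was −0.33 on chromosome 8, −0.28 on chromosome 18, −0.27 on the X chromosome, −0.26 on chromosome 5 and −0.23 on chromosome 3. On the other chromosomes it lay between −0.09 and 0.09. These 5 chromosomes hold 22.6% of the genes, 612 of the 1351 genes that fell (45.3%) and 74 of the 694 that rose (10.7%). Relative to the other chromosomes, their median was shifted by −0.246 to −0.238 in the MU libraries and by −0.0227 to 0.0187 in the WT libraries. The shift was uneven along some chromosomes. On the X chromosome, the 3 blocks of 40 neighbouring genes between 101254528 and 168673898 had medians of −0.66, −0.59 and −0.52, and a block between 53344598 and 74273135 had a median of 0.01. On chromosome 11, the blocks up to 69662642 had medians between 0.10 and 0.20, and all later blocks lay below 0. Other stretches were raised. On chromosome 14, the blocks from 69784990 to 122984035, where Rb1 and Sucla2 lie, had medians of 0.34 and 0.29. An earlier block, from 21031442 to 31371986, had a median of −0.27. On chromosome 1, the blocks up to 71653200 had medians between 0.12 and 0.27. Those from 163779583 on, where Fh1 and Eprs lie, had medians between 0.16 and 0.25. With position centring, an alternative chosen after the data were seen, 2104 genes passed, 939 higher and 1165 lower, and 1805 of them were among the 2667. The lists of nuclear genes that had passed still did. Their camera adjusted p was 0.0103 for antioxidant genes, 5.52e-09 for DNA replication and 0.00192 for p53 targets. It was 0.000175 for matrix, 2.2e-09 for contractile and 0.0402 for inflammatory genes. The mtDNA-encoded mRNAs were left unchanged by this fit, so their camera adjusted p of 0.00851 is no test of position.

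**Figure D4:**
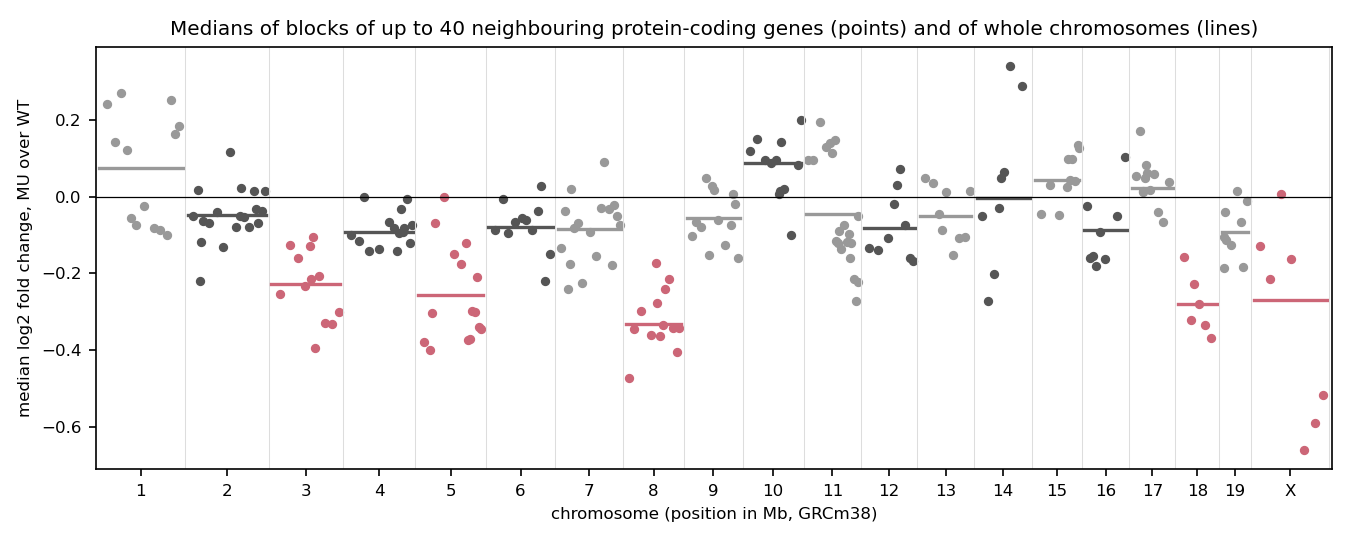
Points are medians of the log2 fold change (MU over WT) over blocks of up to 40 neighbouring protein-coding genes, placed by chromosome and position (GRCm38), and lines are medians over whole chromosomes. Chromosomes 3, 5, 8, 18 and X, in red, have medians between −0.33 and −0.23.

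The authors' deposited table, made from the same libraries, gives an adjusted p under 0.05 to 3582 genes, 1603 higher and 1979 lower in MU. Of 13286 genes in both tests, 2445 were called in both, 942 higher and 1503 lower, and all had the same direction. The overlap of independent lists would be 110 higher and 226 lower genes. The authors' deposited table thus also called 94% of the 2601 limma calls that have an adjusted p there. Log2 fold changes of the tests had a Pearson correlation of 0.885 across genes, which are not independent replicates. Since both use the same 6 libraries, this overlap is no independent evidence. For Tars2 the authors' deposited table gives a log2 fold change of −0.28 with an adjusted p of 0.114, and for Cdkn1a 0.32 with an adjusted p of 0.0478 (the authors' DESeq2).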

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

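The correction for GC content and length and the position-centred fit were chosen after the data were seen, and all other settings were planned. Of 113 named genes, 86 passed at first. Over all settings the named genes gave 1766 values on the same side and with the same sign, 217 calls lost, 32 gained and 9 sign changes, 7 of which had no call on either side. After position centring 67 of the 86 still passed. The values gave no sign that the replicate numbers pair the libraries: deviations of same-numbered libraries correlated at 0.050, 0.015 and −0.074. MU replicate 3 correlated best with WT replicate 2 (0.120) and MU replicate 1 with WT replicate 3 (0.098). With 3 libraries per group these correlations cannot exclude a shared culture or day, on which the labels are silent. With a replicate block, 1093 genes passed, 594 by at least 2-fold, and 56 of the 86 named genes. The block turned G1 regulators to the lower side (adjusted p = 0.972), and ribosomal proteins and interferon-stimulated genes passed with it (0.0393 each). The number of genes passing ranged from 1071 to 3391 with 1 library left out, the highest without WT replicate 2. The number changed by at least 2-fold was 263 with a pseudocount of 5, which shrinks low genes by construction, and 434 with a TPM minimum of 5, where fewer genes are tested. With the correction for GC content and length 3537 genes passed and the mtDNA share differed by 3.16 points. With an estimated correlation 0 lists passed, with adjusted p of 0.59 for mtDNA-encoded mRNAs, 0.206 for antioxidant genes, 0.147 for DNA replication and for p53 targets, 0.214 for matrix and for inflammatory genes and 0.195 for contractile genes. With fry, which does not compare a list with other genes, 13 passed, but mtDNA-encoded mRNAs did not (0.097). Those that passed only with it were mitochondrial chaperones and proteases (0.000555) and muscle markers (0.0265). Quantile normalization ended the calls of mtDNA-encoded mRNAs (0.564), where it removes part of a shared rise by construction, and of antioxidant genes (0.126). A TPM minimum of 5 also ended the call of antioxidant genes (0.0524). With 1 library left out, adjusted p ranged from 0.000151 to 0.0637 for mtDNA-encoded mRNAs, from 0.0103 to 0.0684 for antioxidant genes and from 0.0178 to 0.0929 for inflammatory genes. The overlap with the authors' calls was 890 genes at an adjusted p under 0.01 in both.

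Lists without a call changed direction as follows (adjusted p after the change). Complexes II to V turned lower with no filter (0.764), without WT replicate 1 (0.586), without MU replicate 1 (0.969, and 0.973 without MU replicate 3 with no change of direction), with the GC and length correction (0.906), position-centred (0.917) and with fry (0.429). The ATF4 list turned lower with no filter (0.918), without WT replicate 1 (0.995), WT replicate 3 (0.868) or MU replicate 3 (0.962) and with fry (0.842), and not without MU replicate 2 (0.679). G1 regulators turned lower with no filter (0.582), without WT replicate 1 (0.995) or MU replicate 3 (0.972), position-centred (0.665) and with fry (0.0869), and not without WT replicate 2 (0.882). Cytosolic synthetases and the TCA cycle turned higher with quantile normalization (0.769 each). Log2 fold changes that changed sign were those of Atf4 (0.0144 with quantile normalization) and mt-Nd1 (0.0551 rescaled without mtDNA-encoded genes, 0.0434 with median of ratios, 0.0933 without WT replicate 1, 0.0317 without MU replicate 3). Without WT replicate 2 the value of mt-Nd1 kept its sign (−0.0717). Position centring turned Cars2 (0.065), Prim2 (−0.0838) and Sucla2 (−0.0655), and leaving out WT replicate 2 turned Rfc4 (−0.0872). Without WT replicate 3 the value of Rfc4 kept its sign (0.411). Where no reason is given, the cause was not tested. A test on counts was planned but not run, because the tables used here give none, and with the depth unknown no counting limit can be set for genes listed at 0.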

Other observations

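Chosen after results were seen were the gene families, the tests of a single library and of chance placement for the chromosome shift, and the tests of WT replicate 2 and of a common factor for the mtDNA share, as well as the GC and length correction and the position centring that other tests use. Of 41 families looked through, 12 passed camera after adjustment over them, and 0 did with an estimated correlation. The proteasome, the protease complex that degrades ubiquitinated proteins, was lower in MU: of 36 subunit genes 20 fell and 1 rose, with a median log2 fold change of −0.40 (adjusted p = 1.28e-06, 0.315 with an estimated correlation). Psma5 fell from 421 ± 62.5 to 232 ± 16.0 TPM and Psmd7 from 222 ± 30.8 to 132 ± 1.67 TPM. The exception was Psmb9, a subunit of the immunoproteasome, which rose from 2.95 ± 0.656 to 7.06 ± 2.42 TPM but did not pass without WT replicate 1 (0.0692), WT replicate 2 (0.0602), WT replicate 3 (0.0778), MU replicate 1 (0.0982) or MU replicate 3 (0.0931, limma adjusted p). After position centring 15 subunits fell and 0 rose, and with quantile normalization 11 fell and 1 rose.

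Members of the Prl2c group of the prolactin family, known in proliferating fibroblasts as proliferins, fell: Prl2c2 from 260 ± 24.9 to 46.6 ± 1.56 TPM and Prl2c3 from 127 ± 39.7 to 17.4 ± 3.17 TPM (family adjusted p = 0.00494, camera, 0.315 with an estimated correlation). Their near-identical copies make the split between them uncertain. The chromatin protein genes Hmga1 and Hmga2 fell from 585 ± 262 to 146 ± 11.8 TPM and from 341 ± 52.1 to 128 ± 8.06 TPM (family adjusted p = 0.0112, 0.315 with an estimated correlation), and Hmga1 could share reads with a copy, Hmga1b. Among 14 Wnt ligands, receptors and secreted antagonists, 6 fell and 0 rose (adjusted p = 0.0351, camera, 0.471 with an estimated correlation). Besides Dkk2 these were Dkk3, from 5.62 ± 0.298 to 0.617 ± 0.163 TPM, Wnt5a, from 28.3 ± 4.00 to 13.4 ± 0.955 TPM, Lrp5 (not passing without MU replicate 2, 0.0512), Fzd1 and Sfrp1, which was listed at 0 in all MU libraries. Of 11 serpins, 8 rose and 2 fell, among them Serpinf1, which rose from 552 ± 59.1 to 1121.7 ± 85.3 TPM, and Serpine2, which fell from 9.58 ± 0.655 to 0.139 ± 0.0847 TPM (adjusted p = 0.0107, camera, 0.315 with an estimated correlation). These directions held under each scaling tried.

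The lower medians on chromosomes 3, 5, 8, 18 and X may reflect copy number differences between the lines, as a hypothesis. The shift kept 102% of its size after the correction for GC content and length. It was present in each MU library (highest value −0.238), and neighbouring genes had a Spearman correlation of 0.221 against at most 0.0361 in 1000 shuffles of gene order, which argues against these trends, a single library and chance placement as the cause. A copy number difference should shift less and more abundant genes alike, and the values were −0.241 and −0.25. No DNA was analysed here, so copy number itself and a difference in regulation along these chromosomes stay open.

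The 7 protein-coding genes listed at 0 in all MU libraries, with at least 5 TPM on average in WT, were Gpx7, Pcdh7, Sfrp1, Crtap, Cck, Hs6st2 and Gm1673. Loss of most neighbours at most of these genes is argued against by the 70 nearest genes, whose pooled median log2 fold change was −0.189. Beside single genes the medians ran from −0.354 (Sfrp1) to −0.007 (Crtap). Single neighbours ran from −1.84 (beside Sfrp1) to 1.95 (beside Pcdh7). A pooled median cannot exclude loss of a few neighbours beside 1 gene. Loss of reads in single libraries may contribute, since 14 protein-coding genes in MU and 7 in WT were listed at 0 in only 1 or 2 libraries of a group while the rest averaged at least 5 TPM. The authors' deposited table gives adjusted p of 1.74e-125 for Hs6st2, 6.83e-72 for Crtap, 8.35e-29 for Gpx7 and 2.62e-17 for Gm1673 (DESeq2). For these genes such loss would have to recur in every MU library and in no WT library, which argues against it as the only cause. For comparison, 0 of 1128 values of 188 nuclear genes of respiration, the mitochondrial ribosome, mitochondrial synthetases and the TCA cycle were at 0. On average those genes were more abundant than the 7, which stood at 3.2 to 26.7 TPM in WT. Their values thus say little about estimates at that level. Clonal silencing or a deletion within a gene was not tested.

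The larger share of mtDNA-encoded mRNAs in MU did not rest on WT replicate 2, since without it the lowest MU share stayed 1.48 points above the highest WT share. A correction for GC content and length left 61.4% of the median log2 fold change of the 13 mRNAs, with 54.1% to 94.1% when each library was left out. This trend could thus account for part of it. After the correction 3 of the 13 passed (limma), and their list passed camera (adjusted p = 0.0324). The correction rests mostly on nuclear genes with more GC (median 49.5% in tested protein-coding genes, 37.1% in the 13), so the size of the remainder is uncertain. Whether 1 common factor moved all mRNAs stays open: 0 of the 13 passed as deviating from their shared shift, but deviations ran from −0.44 (mt-Nd1) to 0.50 (mt-Nd4l, adjusted p = 0.0504, limma) and 3 libraries per group leave such differences undecided. More mtDNA, more transcription, slower decay and a different yield in the libraries were not tested.

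Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many passing genes (2667, highest other 2), as many with at least 2-fold (712, highest other 2) and as many passing lists (7, highest other 4). The other splits mix WT and MU libraries unevenly, so they keep part of the difference between the lines and put the rest into the spread. Their numbers are thus not what would be found without any difference. As 10 splits cannot give a share under 0.05, no more can be said from them.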
